A study of Mus musculus with 12 samples.

How the data were processed

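Bulk RNA sequencing was analysed for 12 libraries of bone marrow-derived macrophages from male C57BL/6J mice aged 8 weeks. Bone marrow-derived macrophages are primary macrophages grown from marrow progenitors. The cells had received a control siRNA (siControl) or an siRNA against Ehd1 (siEhd1) and were left unstimulated (M0, called resting here) or treated with lipopolysaccharide (M1, called LPS-treated here), with 3 libraries in each of the 4 groups. Lipopolysaccharide (LPS) is a cell wall component of Gram-negative bacteria that activates Toll-like receptor signalling. Per the labels' protocols, total RNA was taken with a column kit and libraries were made after polyA enrichment. The dose and duration of LPS, the siRNA sequences and the time after transfection are not given in the sources used here.

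The authors deposited raw counts per gene symbol in 2 tables, 1 for the resting and 1 for the LPS-treated libraries, with 24421 genes each in the same order. Per the submitters' processing notes, the build was mm10 and the tools named were FastQC 0.10.1, Trim Galore 0.6.3 with cutadapt, STAR 2.7.6a, featureCounts 2.20.0, DESeq2 1.46.0 and R 4.4.2. The annotation, the strand setting and the treatment of reads that map to several genes are not given in the sources used here. Counts of near-identical genes such as Ifit3 and Ifit3b, Pydc3 and Pydc4, class I histocompatibility genes, Ly6 family genes and ribosomal protein genes are therefore uncertain where reads could be split between copies. Library totals ranged from 18572725 to 22545272 counts. Columns were matched to samples through the library names in the labels, and 0 columns were left unused.

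Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1). Genes were kept by filterByExpr with group as its argument (minimum count 10, minimum total 15), which left 12164 of the 17270 genes with at least 1 count. The genes removed held at most 0.039% of any library's counts. TMM factors, robust dispersion estimates and a quasi-likelihood fit with 1 mean per group over all 12 libraries gave 8 residual degrees of freedom and a common biological coefficient of variation of 0.0588. Each contrast was tested with the quasi-likelihood F test, Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05; all adjusted p-values for genes come from this edgeR test unless another tool is named. Log2 fold changes are siEhd1 relative to siControl, or LPS-treated relative to resting, and SE is the absolute log2 fold change divided by the square root of F. Levels are in CPM, counts scaled to a common library size by the cpm function of edgeR with TMM factors, given as mean ± SD over 3 libraries.

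The contrasts were siEhd1 against siControl in resting cells, the same in LPS-treated cells, the difference between those effects, LPS-treated against resting cells with siControl, and the LPS effect averaged over both siRNAs. The tables were not normalized before deposit, so all libraries entered 1 fit. Resting and LPS-treated libraries came in separate tables and the labels give no batch, so any handling that differed between the tables cannot be separated from LPS treatment. The labels do not say whether replicates came from separate animals or cultures; the p-values measure only the spread between these libraries, which may be technical. Within groups, pairs of libraries differed by more than sampling noise (chi-square per degree of freedom from 3.102 to 24.84), and none held identical values.

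The design, the 30 gene lists, the rule for named genes and all but 1 of the alternatives were fixed before the data were examined. Lists with at least 5 measured members (28 lists) were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists in a comparison. Camera was repeated with an estimated correlation, and the directional test fry was run beside it. Where a list's call was lost with the estimated correlation, that adjusted p is printed. The list of mitochondrially encoded genes had 0 members in the tables and is not analysed here, and the erythroid and mast cell list had 2 measured members and was counted but not tested. LPS-induced and LPS-repressed sets held genes called in the averaged LPS contrast with an absolute log2 fold change of at least 1.

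Named genes were Ehd1 to Ehd4 and Sort1; the 10 largest changes per direction among called genes with a mean of at least 5 CPM in a compared group and, outside the difference contrast, no overlap between the groups' libraries; up to 4 called members per list with the smallest p; and 9 inflammatory or lipid genes named whether called or not. Predicted gene models, pseudogenes and mitochondrial, histone and ribosomal protein genes were left out of the ranking by size. Genes named outside this rule are said to be so. A fold against a group with 0 counts is a lower bound, computed against 3 counts over the group. With 1 to 3 counts in a group the ratio is given with its 95% exact binomial interval, which covers counting error only.

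Gene positions and 3 prime UTR sequences came from GENCODE release M21 on GRCm38, the assembly also called mm10. Of the 24421 symbols, 23376 were found in that annotation, and 11731 of the 12164 tested genes. After the siEhd1 effects had been fitted, every 7-base sequence found in the longest annotated 3 prime UTR of at least 50 genes was scored for whether genes carrying it had lower log2 fold changes. This search covered 16079 sequences and the 11151 tested genes (91.7%) with a 3 prime UTR of at least 50 bases. Scores are z values from regressions on the presence of the sequence with covariates of the UTR and the mean level, scaled to the spread over all the sequences.

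Alternatives were median-of-ratios size factors, no filter on low counts, a stricter filter (1 CPM in every library of a group), the DESeq2 1.42.0 Wald test, limma-voom, the replicate number as a block, fits within each table, leaving out each library in turn, LPS sets at an absolute log2 fold change of at least 2, and the other set tests. A fit without the genes that carry the best-scoring 7-base sequence was added after seeing the data. The procedure was tested on simulated counts drawn with the real dispersions and with 200 genes changed. Means per gene were taken over each state for the siEhd1 contrasts and over all 12 libraries for the LPS contrasts. Fewer genes were changed than were called in the real contrasts, so error rates at that scale were not tested. For the resting siEhd1 contrast (12090 genes tested) it recovered 75 of 100 genes changed by 1.5-fold and 89 of 100 changed by 2-fold, with 17 false calls (9.4% of calls). For the LPS-treated contrast (12087 genes) it recovered 76 of 98 and 81 of 99 with 12 false calls (7.1% of calls). For the difference contrast (12083 genes) it recovered 60 of 99 and 79 of 100 with 12 false calls (7.9%). For LPS with siControl (11948 genes) it recovered 77 of 97 and 86 of 99 with 6 false calls (3.6%). The averaged LPS contrast (11973 genes) gave 89 and 94 of 97 changed genes at each fold, with 11 false calls.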

Results

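The series measured polyA RNA in mouse bone marrow-derived macrophages to ask what EHD1, a protein of endocytic recycling, does to inflammatory gene expression, with sortilin and atherosclerosis as the stated context. The 12 libraries formed 4 groups of 3, resting or LPS-treated with siControl or siEhd1. Library totals lay between 18572725 and 22545272 counts, and 14119 to 14753 genes were detected per library.

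Ehd1 was lower in every siEhd1 library than in every siControl library of the same state. The gene (ENSMUSG00000024772.9) lies on chromosome 19 from 6276725 to 6300096 on the plus strand of GRCm38. In resting cells Ehd1 stood at 53.2 ± 1.18 CPM with siControl and 31.5 ± 2.35 CPM with siEhd1 (SD, n = 3 each), or 59.2% of control (log2 fold change -0.76, SE 0.08, edgeR adjusted p = 5.7e-07). After LPS it stood at 619.7 ± 64.5 and 301.8 ± 18.2 CPM, or 48.7% of control (-1.04, SE 0.07, edgeR adjusted p = 2.5e-08). LPS itself raised Ehd1 in siControl cells by 3.54 on the log2 scale, so LPS-treated siEhd1 cells held more Ehd1 RNA than resting siControl cells. The siEhd1 effect on Ehd1 did not differ between states by the test of the difference (-0.28, SE 0.10, edgeR adjusted p = 0.12).

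Among the paralogs, Ehd2 and Ehd3 were below the count filter. Ehd4 had log2 fold changes of 0.04 in resting cells (edgeR adjusted p = 0.65) and 0.20 in LPS-treated cells (edgeR adjusted p = 0.028). The latter call was lost without M1_siCON replicate 1 or 2 or M1_siEHD1 replicate 2 or 3 (adjusted p up to 0.14; range over all alternatives 0.0065 to 0.14). Sort1, which encodes the sorting receptor sortilin (chromosome 3, 108284082 to 108361511, plus strand), fell in resting cells from 102.1 to 70.8 CPM, to 69.4% of control (-0.53, SE 0.07, edgeR adjusted p = 8e-06). After LPS the levels were 15.4 and 14.2 CPM (-0.12, SE 0.09, edgeR adjusted p = 0.50). LPS lowered Sort1 in siControl cells by a log2 fold change of -2.73. The difference of the siEhd1 effects on Sort1 was 0.41 (SE 0.11, edgeR adjusted p = 0.037). That call was lost with limma-voom and without any 1 of 8 libraries (M0_siCON replicates 1, 2 and 3, M0_siEHD1 replicate 1, M1_siCON replicates 1 and 3, M1_siEHD1 replicates 2 and 3), with adjusted p from 0.017 to 0.12 over the alternatives.

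**Figure D1:**
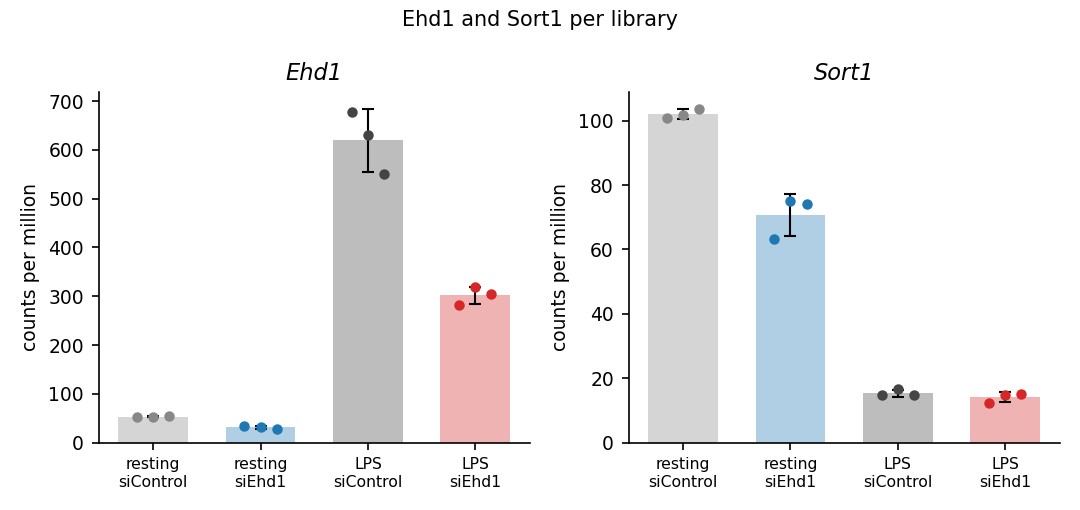
CPM of Ehd1 (left) and Sort1 (right) in each library; bars are group means, error bars SD over 3 libraries and points single libraries. Ehd1 was 59.2% of control in resting and 48.7% in LPS-treated siEhd1 cells, and Sort1 69.4% and 92.2%.

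In resting macrophages, interferon-stimulated genes were lower and cell cycle genes higher with siEhd1 than with siControl. Untransfected libraries were not among the samples, so which of the siRNAs moved these genes cannot be told. Of 48 measured interferon-stimulated genes, 44 fell, 0 rose and 4 were not called (44 lower adjusted over the list alone), with a median log2 fold change of -0.66. The antiviral sensor-pathway genes Oasl2 (-1.01, SE 0.06, 334.9 to 165.9 CPM) and Oas3 (-0.92, SE 0.06), the transcription factor Irf7 (-0.88, SE 0.07) and the nucleic acid sensor Zbp1 (-1.12, SE 0.08) had the smallest p-values. Ifi44 (-1.36, SE 0.10), Ifit2 (-1.32, SE 0.19), Ifit3b (-1.22, SE 0.15), Ifit3 (-1.16, SE 0.15), Pydc3 (-1.29, SE 0.15), Pydc4 (-1.16, SE 0.11) and Slfn1 (-1.29, SE 0.13) were among the 10 largest decreases. Counts of the Ifit3 and Pydc3 pairs are uncertain because their copies are near-identical. The list was lower than other genes by camera (adjusted p = 5.9e-42), but with adjusted p = 0.11 with an estimated correlation.

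Of 34 cell cycle genes, 33 rose, 0 fell and 1 was not called (34 higher adjusted over the list alone), with a median of 1.36. The mitotic genes Bub1b (1.21, SE 0.08), Kif23 (1.09, SE 0.08), Birc5 (1.67, SE 0.12) and Ccnb2 (1.45, SE 0.11) had the smallest p-values. Pbk (2.07, SE 0.18), Prr11 (1.99, SE 0.13), Ccne2 (1.98, SE 0.25), Ankle1 (1.97, SE 0.20), the ribonucleotide reductase gene Rrm2 (1.97, SE 0.24), Shcbp1 (1.95, SE 0.17) and Anln (1.90, SE 0.13) were among the 10 largest increases. The camera adjusted p was 9.1e-65, and adjusted p = 0.062 with an estimated correlation. The Rrm2 call was lost with the replicate number as a block within the resting table. Beside these genes, 6 of 9 osteoclast markers rose and 0 fell (camera adjusted p = 0.0012, adjusted p = 0.30 with an estimated correlation), and 14 of 27 macrophage identity genes fell. Of 35 measured markers of neutrophils, dendritic cells, lymphocytes, stromal and endothelial cells and erythroid or mast cells, 4 were higher and 6 lower, and 9 lay at 5 CPM or more in resting siControl cells. Outside these groups, the Langerhans cell lectin gene Cd207 (2.27, SE 0.18) and Cyp2s1 (1.95, SE 0.17) rose, and Nat8l (-1.21, SE 0.14) and the iron exporter gene Slc40a1 (-1.18, SE 0.15) fell.

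Genes of macrophage identity and antigen presentation were lower in resting siEhd1 cells. Of 27 identity genes 14 fell and 0 rose (the same numbers adjusted over the list alone; median -0.21, camera adjusted p = 2.2e-05, adjusted p = 0.30 with an estimated correlation). These included the Fc receptor Fcgr1 (-0.80, SE 0.05), the transcription factor Cebpa (-0.64, SE 0.07) and the efferocytosis receptor Mertk (-0.60, SE 0.07). Of 23 antigen presentation genes 13 fell and 0 rose (13 and 1 adjusted over the list alone; median -0.24, camera adjusted p = 3e-06, adjusted p = 0.30 with an estimated correlation). These included the peptide transporters Tap1 (-0.56, SE 0.06) and Tap2 (-0.43, SE 0.06). In the inflammatory cytokine and chemokine list 10 of 27 rose, 0 fell and 17 were not called (10 higher and 1 lower adjusted over the list alone; median 0.36, camera adjusted p = 0.069). The monocyte chemokine Ccl2 rose from 4.404 to 25.56 CPM (2.53, SE 0.43, edgeR adjusted p = 0.0027), a call lost among the alternatives run only with the replicate number as a block within the resting table (adjusted p = 0.15; range 3.1e-08 to 0.15). Il1b (-0.51), Il10 (0.40) and Nos2 were not called, and Il6 was listed at 0 in resting siControl cells. Ccl22 (1.36, SE 0.30) and Ccl9 (0.54, SE 0.09) rose too, and Tnf rose by 0.36 (SE 0.09), a call lost without M0_siEHD1 replicate 1 (adjusted p = 0.058; range over the alternatives 0.0026 to 0.058).

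Genes of cholesterol handling moved both ways. In the list of cholesterol efflux and LXR targets 10 of 25 fell and 2 rose (12 and 2 adjusted over the list alone; median -0.13, camera adjusted p = 0.096). Apolipoprotein E (Apoe) fell from 5668 to 3307 CPM (-0.78, SE 0.10), the cholesterol transporter Abca1 from 573.4 to 394.2 CPM (-0.54, SE 0.06), and the desaturase gene Scd2 rose (1.07, SE 0.09). Of 18 lipid uptake and scavenger receptor genes 5 fell and 2 rose (7 and 2 adjusted over the list alone; median -0.15, camera adjusted p = 0.055). The fatty acid binding protein genes Fabp4 (-0.79, SE 0.10) and Fabp5 (-0.60, SE 0.07) were lower, and the scavenger receptor gene Cd36 was not called (0.19, SE 0.24). Of 25 cholesterol biosynthesis genes 7 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.18, camera adjusted p = 0.069), with Idi1 (0.58, SE 0.11) and Hsd17b7 (0.58, SE 0.11) among them.

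Other lists called in resting cells were nuclear genes of mitochondrial respiration (17 of 30 higher, 1 lower, median 0.19, camera adjusted p = 0.0012) and ribosomal protein genes (14 of 79 higher, 1 lower, median 0.13, 0.0012). Called as well were osteoclast markers (6 of 9 higher, 0 lower, median 0.32, 0.0012), the unfolded protein and integrated stress response (6 of 26 higher, 0 lower, median 0.13, 0.031), NF-kB pathway and feedback (2 of 30 higher, 10 lower, median -0.07, 0.031) and Toll-like receptor signalling (1 of 28 higher, 10 lower, median -0.12, 0.031). With an estimated correlation these 6 lists had, in that order, adjusted p = 0.59, 0.59, 0.30, 0.59, 0.47 and 0.55. The stress response call was lost without M0_siCON replicate 1 or M0_siEHD1 replicate 2 (adjusted p up to 0.092; range over all alternatives 0.011 to 0.59), the NF-kB call without M0_siCON replicate 1 or 2 (up to 0.067; 0.0036 to 0.47) and the Toll-like receptor call without M0_siCON replicate 1 or M0_siEHD1 replicate 1 (up to 0.063; 0.0048 to 0.55). Not called were endocytic recycling (4 higher and 6 lower of 25, median 0.02, mean -0.04), sortilin family and retromer sorting (3 and 6 of 24) and alternative activation (7 and 2 of 22). The same held for integrins (8 and 2 of 25), lysosome and autophagy (2 and 7 of 31), glycolysis (8 and 6 of 25), heat shock and immediate early genes (9 and 5 of 26) and p53 targets (2 and 7 of 25). It also held for NRF2 (6 and 2 of 21), tissue repair (6 and 5 of 23), neutrophil (0 and 1 of 7), dendritic (3 and 2 of 10), lymphocyte (0 and 1 of 5) and stromal markers (0 and 2 of 11). The erythroid and mast cell list had 1 of 2 higher.

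In all, 1704 genes were higher and 1728 lower with siEhd1 in resting cells (28.2% of the 12164 tested), with 283 and 55 of these changed at least 2-fold. Without M0_siCON replicate 1 the lower count was 1148. A 7-base sequence, GCCTTGT, was frequent in 3 prime UTRs of the lower genes: 444 of 1619 lower genes with a searched UTR carried it (27.4%), against 11.4% of other genes and 8.4% of higher genes. Oasl2 and Cebpa carried it, whereas Sort1, Ehd1 and most interferon-stimulated genes did not (5 of 48 did). Among the 43 without it the median was -0.61 and 40 were called lower, and among the 31 cell cycle genes without it the median was 1.36.

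**Figure D2:**
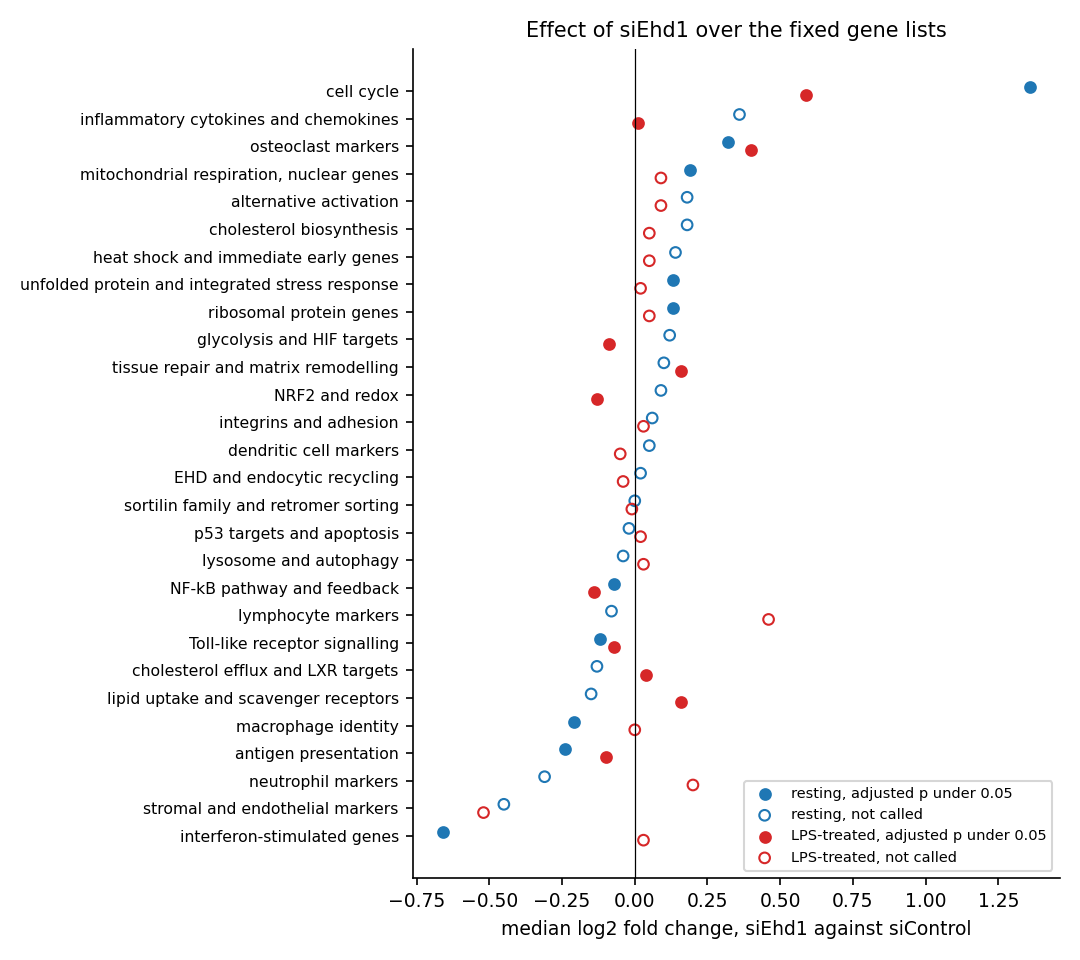
Median log2 fold change of siEhd1 against siControl over each tested gene list, in resting (blue) and LPS-treated (red) cells; filled points had a camera adjusted p under 0.05 at the preset correlation. The cell cycle list lay at 1.36 and 0.59, and the interferon-stimulated list at -0.66 and 0.03.

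In LPS-treated macrophages 22 of 34 cell cycle genes rose with siEhd1, 0 fell and 12 were not called (33 higher adjusted over the list alone), with a median of 0.59 (camera adjusted p = 3.9e-30, adjusted p = 0.17 with an estimated correlation). Bub1b (0.58, SE 0.09), Kif23 (0.70, SE 0.12), Mcm6 (0.43, SE 0.07) and Plk1 (0.92, SE 0.15) led them. Beside these genes, 3 of 9 osteoclast markers rose and 0 fell. The interferon-stimulated list had 1 of 48 higher and 1 lower (median 0.03), the higher being the chemokine gene Cxcl10 (0.70, SE 0.13).

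Of 30 NF-kB pathway and feedback genes 6 fell, 0 rose and 24 were not called (10 lower adjusted over the list alone; median -0.14, camera adjusted p = 3.4e-07, adjusted p = 0.13 with an estimated correlation). These included Tnfaip2 (-0.52, SE 0.05) and the inhibitor gene Nfkbie (-0.33, SE 0.05). Interleukin-1 beta (Il1b) stood at 1342 CPM with siControl and 971.4 CPM with siEhd1 (-0.47, SE 0.10, edgeR adjusted p = 0.011). That call was lost with DESeq2 and without M1_siCON replicate 2 or M1_siEHD1 replicate 3, with adjusted p from 0.00096 to 0.19 over the alternatives. Not called were Tnf (-0.05, SE 0.07), Nos2 (-0.23, SE 0.16), Il6 (-0.43, SE 0.35), Il10 (0.81, SE 0.36), Ccl2 (0.78, SE 0.28), Cd36 (0.22, SE 0.24), Abca1 (-0.13, SE 0.06) and Arg1 (0.31, SE 0.20). The chemokine genes Ccl12 (17.36 ± 0.76 to 47.62 ± 2.26 CPM), Ccl4 (0.55, SE 0.09) and Ccl3 (0.44, SE 0.08) rose. In the cytokine and chemokine list as a whole 5 of 27 rose and 3 fell (median 0.01, camera adjusted p = 0.024, adjusted p = 0.45 with an estimated correlation), a call lost without M1_siCON replicate 1 or M1_siEHD1 replicate 1 or 2 (adjusted p up to 0.35; range over all alternatives 0.0057 to 0.45).

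Beside Ccl12, given above, the largest increases after LPS were in the matrix metalloproteinase gene Mmp9 (11.9 to 36.3 CPM, 1.61, SE 0.19), Tmem119 (1.53, SE 0.19), the endothelial lipase gene Lipg (1.52, SE 0.19), the metallothionein gene Mt2 (1.40, SE 0.11), Slc13a3 (1.37, SE 0.10), Myrf (1.31, SE 0.18) and the collagen cross-linking enzyme gene Lox (1.12, SE 0.13). Ptprn (1.47, SE 0.37) and the cyclin gene Ccnd1 (1.15, SE 0.27) were also among them, but Ptprn was called without M1_siCON replicate 3 and Ccnd1 without M1_siEHD1 replicate 3 and neither without any other 1 of the LPS-treated libraries (adjusted p up to 0.12 and 0.10; ranges over all alternatives 0.018 to 0.21 and 9.1e-05 to 0.10). The tissue repair and matrix list had 5 of 23 higher and 0 lower (median 0.16, camera adjusted p = 0.00043, adjusted p = 0.45 with an estimated correlation). The osteoclast list had 3 of 9 higher and 0 lower (median 0.40, camera adjusted p = 0.00043, adjusted p = 0.20 with an estimated correlation). The efflux list had 5 of 25 higher and 0 lower (median 0.04, camera adjusted p = 0.0039, adjusted p = 0.36 with an estimated correlation). The lipid uptake list had 1 of 18 higher (median 0.16, camera adjusted p = 0.0039, adjusted p = 0.17 with an estimated correlation). A lower list was NRF2 and redox (5 of 21 lower, 1 higher, median -0.13, camera adjusted p = 0.00043, adjusted p = 0.24 with an estimated correlation). In it, the glutathione reductase gene Gsr (-0.46, SE 0.05) and Nfe2l2 (-0.30, SE 0.05) fell. Another was antigen presentation (4 of 23 lower, 1 higher, median -0.10, camera adjusted p = 0.0061, adjusted p = 0.45 with an estimated correlation). Toll-like receptor signalling (2 of 28 lower, 0 higher, median -0.07, camera adjusted p = 0.03, adjusted p = 0.45 with an estimated correlation) lost its call without M1_siCON replicate 3 or M1_siEHD1 replicate 1 (adjusted p up to 0.25; 0.0099 to 0.45). Glycolysis (3 of 25 lower, 0 higher, median -0.09, camera adjusted p = 0.015, adjusted p = 0.57 with an estimated correlation) lost its call without M1_siCON replicate 1 (0.25; 5.6e-05 to 0.57). Neutrophil markers had a positive median (0.20) and a downward test (camera adjusted p = 0.19).

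In all, 540 genes were higher and 499 lower after LPS (8.54% of those tested; 31 and 6 at least 2-fold). Without M1_siEHD1 replicate 1 these counts were 304 and 303. GCCTTGT was carried by 231 of 474 searched lower genes (48.7%), against 12.2% of other genes and 9.8% of higher genes. Of the 10 largest decreases, Lrp11 (-0.81, SE 0.12), Fgl2 (-0.73, SE 0.08), Gpr85 (-0.69, SE 0.07), Emc2 (-0.68, SE 0.08), Dtwd1 (-0.67, SE 0.15), Iars (-0.67, SE 0.07) and Tor1b (-0.65, SE 0.06) carried it, and Slc40a1 (-1.10, SE 0.18), Ehd1 and Ly6i (-0.69, SE 0.11) did not. With all carriers left out of the fit, a choice made after seeing the data, 256 genes were lower and 385 higher.

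**Figure D3:**
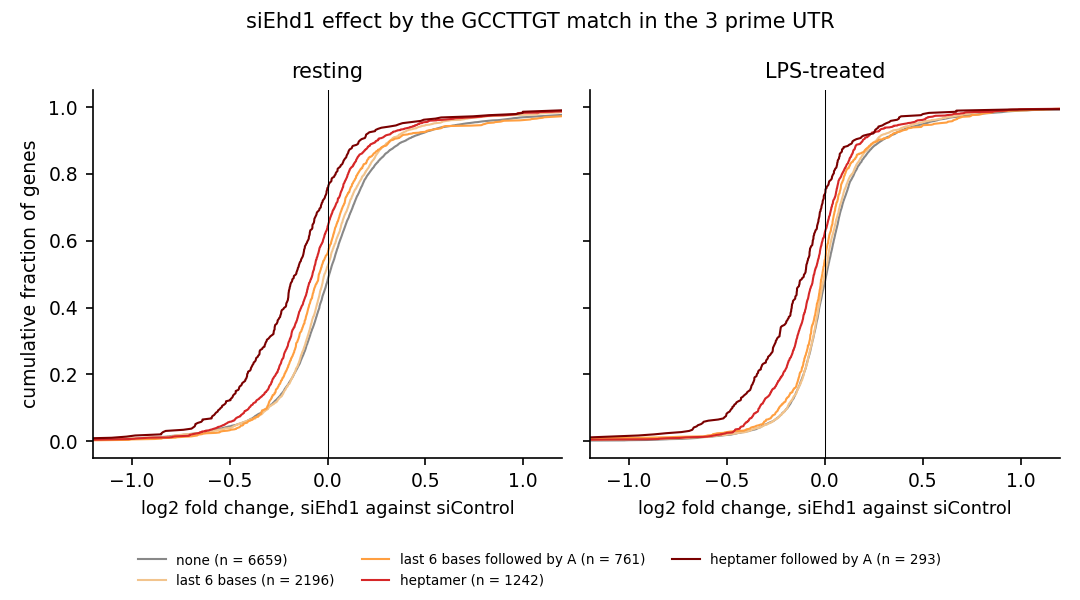
Cumulative distribution of the log2 fold change of siEhd1 against siControl in resting (left) and LPS-treated (right) cells, by the longest match to GCCTTGT in the 3 prime UTR. Median values for genes with the full sequence followed by A were -0.16 and -0.102, against 0.009 and 0.008 for genes with no match; the tails lie beyond the axis.

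The effects in both states overlapped. Of the genes tested, 305 were higher in both states (75.6 by independent lists, 2-sided Fisher's exact p = 8.9e-126) and 321 lower in both (70.9, 2-sided Fisher's exact p = 8.7e-155). Another 8 were higher in resting and lower in LPS-treated cells (69.9 by independent lists) and 28 the opposite (76.7). Across genes, which are not independent replicates, the effects had a Pearson r of 0.391 and a Spearman rho of 0.413. Of 303 searched genes lower in both states, 181 (59.7%) carried GCCTTGT, against 12.5% of other genes, and with carriers left out 144 genes were lower and 223 higher in both. Without M1_siEHD1 replicate 1, 186 genes were higher in both.

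**Figure D4:**
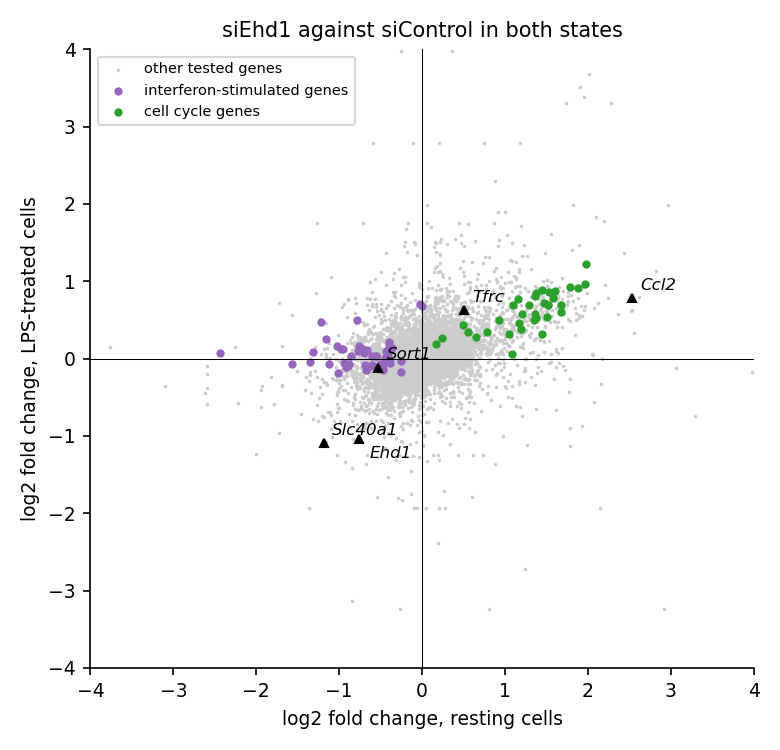
Log2 fold change of siEhd1 against siControl in resting (horizontal) and LPS-treated (vertical) cells for each tested gene; 2 genes beyond 4 on either axis are not shown. Of 48 interferon-stimulated genes (purple) 44 were called lower in resting cells and 1 after LPS, and of 34 cell cycle genes (green) 33 were called higher in resting cells and 22 after LPS.

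The siEhd1 effect on interferon-stimulated genes differed between states. Of 48 genes, 36 had a higher (less negative) effect after LPS, 0 a lower one and 12 no called difference (44 adjusted over the list alone; median difference 0.66, camera adjusted p = 4.8e-68, adjusted p = 0.029 with an estimated correlation). Ifi44 (1.31, SE 0.13), Zbp1 (1.04, SE 0.11), Oasl2 (0.82, SE 0.08) and Oas3 (0.81, SE 0.08) had the smallest p-values. LPS raised these genes in siControl cells, Irf7 for example from 326.2 to 2428 CPM, and Irf7 stood at 2314 CPM with siEhd1 after LPS. Lipid uptake genes also differed (5 of 18 higher, 0 lower, 10 higher adjusted over the list alone, median 0.29, camera adjusted p = 1.7e-07, adjusted p = 0.026 with an estimated correlation), with Fabp4 (1.09, SE 0.14), Fabp5 (0.76, SE 0.09), Mertk (0.53, SE 0.10) and Plin2 (0.38, SE 0.08). The efflux list also differed (5 of 25 higher, 0 lower, median 0.19, camera adjusted p = 3.1e-06, adjusted p = 0.10 with an estimated correlation), with Apoe (1.04, SE 0.13). So did macrophage identity (8 of 27 higher, 0 lower, median 0.22, camera adjusted p = 5.6e-09, adjusted p = 0.10 with an estimated correlation), with Fcgr1 (0.92, SE 0.07).

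The rise of cell cycle genes was smaller after LPS: 14 of 34 had a lower effect and 0 a higher one (28 lower adjusted over the list alone, median -0.73, camera adjusted p = 2.5e-23, adjusted p = 0.15 with an estimated correlation). Birc5 (-1.07, SE 0.19), Aurka (-1.02, SE 0.15), Cdk1 (-0.96, SE 0.17) and Bub1b (-0.63, SE 0.12) led them. NRF2 and redox genes (4 of 21 lower, 0 higher, median -0.20, camera adjusted p = 5e-06, adjusted p = 0.10 with an estimated correlation) and glycolysis genes (6 of 25 lower, 1 higher, median -0.20, camera adjusted p = 6.7e-05, adjusted p = 0.43 with an estimated correlation) also had lower effects, with the thioredoxin reductase gene Txnrd1 (-0.58, SE 0.09) and Pgk1 (-0.67, SE 0.12). Antigen presentation (3 of 23 higher, median 0.14, camera adjusted p = 0.00054, adjusted p = 0.36 with an estimated correlation) and the stress response (4 of 26 lower, median -0.05, camera adjusted p = 0.0017, adjusted p = 0.43 with an estimated correlation) were also called. Ribosomal protein genes (2 of 79 lower, median -0.09, camera adjusted p = 0.0027, adjusted p = 0.73 with an estimated correlation) lost the call without M0_siCON replicate 1 or M1_siCON replicate 1 (adjusted p up to 0.51; 1.3e-07 to 0.73). Mitochondrial respiration (0 of 30, median -0.10, camera adjusted p = 0.01, adjusted p = 0.73 with an estimated correlation) lost its call without M1_siCON replicate 1 (0.16; 0.00035 to 0.73). Lysosome (median 0.10, camera adjusted p = 0.043, adjusted p = 0.73 with an estimated correlation) and neutrophil markers (median 0.56, camera adjusted p = 0.043, adjusted p = 0.34 with an estimated correlation) lost theirs without 6 and 5 libraries each taken alone. These were M0_siCON replicate 3, M0_siEHD1 replicates 1 and 3, M1_siCON replicates 1 and 3 and M1_siEHD1 replicate 2 for lysosome (up to 0.23; 0.01 to 0.73). They were M0_siCON replicate 1, M0_siEHD1 replicates 2 and 3, M1_siCON replicate 1 and M1_siEHD1 replicate 2 for neutrophil markers (up to 0.10; 0.016 to 0.34). In all, 379 genes had a higher and 356 a lower effect after LPS, 264 of the former called lower in resting cells alone and 265 of the latter called higher in resting cells alone. These counts were 243 and 210 without M0_siEHD1 replicate 1, and the lower count was 209 without M0_siCON replicate 1, 221 without M0_siEHD1 replicate 2, 235 without M1_siEHD1 replicate 1 and 236 without M1_siEHD1 replicate 3. GCCTTGT carriers had a median difference of 0.014, and genes with neither it nor its last 6 bases -0.006.

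LPS changed most tested genes in siControl cells, with 4237 higher and 4132 lower (68.8%; 1062 and 1425 at least 2-fold). All 27 measured inflammatory cytokines and chemokines rose (median 5.15, or 4.91 with 3 genes at their lower bounds, camera adjusted p = 9.4e-23, adjusted p = 0.019 with an estimated correlation). Il1b rose from 1.10 to 1342 CPM (10.25, SE 0.18), Tnf from 8.67 to 41.4 CPM (2.25, SE 0.08), Cxcl3 at least 4020-fold and Il6 at least 22.6-fold. The nitric oxide synthase gene Nos2 had a ratio of 6890 (95% interval 1910 to 56900) and the formyl peptide receptor gene Fpr1 a ratio of 9280 (2570 to 76600). The acute phase gene Saa3 (13.79, SE 0.39), Cd38 (12.07, SE 0.14), Lcn2 (10.78, SE 0.13), Irg1 (10.38, SE 0.12) and Serpinb2 (at least 2400-fold) were among the largest increases.

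Of 30 NF-kB pathway and feedback genes 26 rose and 2 fell (median 1.77, camera adjusted p = 4.4e-25, adjusted p = 0.0022 with an estimated correlation), with Sod2 at 4.89 (SE 0.07) and Traf1 at 2.76 (SE 0.07). Interferon-stimulated genes rose in 47 of 48 cases (median 1.67, camera adjusted p = 3.4e-30, adjusted p = 0.12 with an estimated correlation). Glycolysis and HIF targets rose in 21 of 25, with 3 lower (median 1.83, camera adjusted p = 4.7e-21, adjusted p = 0.068 with an estimated correlation), Hif1a at 3.19 (SE 0.06) and Pfkfb3 at 4.43 (SE 0.07). Lipid handling genes moved both ways: 5 of 18 uptake genes rose, 10 fell (median -0.32, mean 0.32). Msr1 was at 3.17 (SE 0.08). In the efflux list 8 of 25 rose and 14 fell, with Abca1 at 1.43 (SE 0.07), Pparg at -4.68 (SE 0.12) and Lipa at -2.22 (SE 0.08). The largest decreases included the prostaglandin dehydrogenase gene Hpgd (-10.08, SE 0.30), Nptx1 (ratio 1700, 582 to 8250), Slco2b1 (-8.05, SE 0.21), Angptl4 (-7.70, SE 0.30) and Mamdc2 (-7.55, SE 0.15). Other called lists were antigen presentation (15 of 23 higher, 6 lower; 0.00057, adjusted p = 0.35 with an estimated correlation), the stress response (21 of 26 higher, 2 lower; 3.6e-05, adjusted p = 0.33 with an estimated correlation), mitochondrial respiration (26 of 30 higher, 0 lower; 0.0026, adjusted p = 0.61 with an estimated correlation), NRF2 (14 of 21 higher, 4 lower; 0.0026, adjusted p = 0.33 with an estimated correlation), tissue repair (11 of 23 higher, 9 lower; 0.0014, adjusted p = 0.61 with an estimated correlation) and neutrophil markers (5 of 7 higher, 0 lower; 1.2e-05, adjusted p = 0.041 with an estimated correlation). Averaged over both siRNAs, 4572 genes were higher and 4743 lower with LPS.

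The siEhd1 effect was then set against the 1051 genes induced and 1400 repressed by LPS. In resting cells LPS-induced genes were lower with siEhd1 (median -0.081, against -0.01 in other genes; 264 called lower and 120 higher, camera adjusted p = 0.0022). In LPS-treated cells they were also lower (median -0.046; 111 lower and 49 higher, camera adjusted p = 0.019), a call lost without M1_siEHD1 replicate 1 (adjusted p = 0.058; range over the alternatives 4.1e-05 to 0.058). LPS-repressed genes were higher with siEhd1 after LPS (median 0.128; 146 higher and 26 lower, camera adjusted p = 1.4e-05). In resting cells their median was 0.003 (302 higher, 224 lower) and the set was not called (camera adjusted p = 0.06). It was called without M0_siCON replicate 1 (adjusted p = 0.021) or M0_siEHD1 replicate 3 (0.04), with a range over the alternatives of 0.01 to 0.2. For the difference of effects the median of induced genes was 0.059 (camera adjusted p = 0.015), but 0.02 without M0_siCON replicate 2 (adjusted p = 0.042; range over all alternatives 2.5e-05 to 0.042). The median of repressed genes was 0.102 (camera adjusted p = 0.019, and adjusted p = 0.13 with an estimated correlation). That call was lost without M1_siCON replicate 1 (median 0.084, adjusted p = 0.11) or M1_siEHD1 replicate 1 (median 0.056, adjusted p = 0.063), with a range over all alternatives of 0.0093 to 0.13.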

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

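The tests of the interferon and cell cycle patterns and of base composition were chosen after the result was seen, whereas the search for a shared siRNA seed and the counts over other splits of the libraries were not. The test of the difference between states called 735 genes. The lists flagged were those called with an estimated correlation too, the interferon-stimulated list (median difference 0.66) and the lipid uptake list (0.29). Other lists given above, cell cycle and macrophage identity among them, were called at the preset correlation only. Named genes were flagged only from the largest changes, the genes always named and the interferon, cell cycle and lipid uptake lists. Named genes of other lists, such as Apoe and Fcgr1, are given above. Flagged genes with a higher effect after LPS were Mamdc2 (1.81), Ifit3b (1.70), Tnfsf10 (1.65), Flt1 (1.60), Iigp1 (1.5), Pdgfc (1.45), Pydc3 (1.44), Ifit3 (1.41), Ifit2 (1.40), Olfr56 (1.36), Ifi44 (1.31), Fabp4 (1.09), Zbp1 (1.04), Oasl2 (0.82), Oas3 (0.81), Fabp5 (0.76), Mertk (0.53), Sort1 (0.41), Abca1 (0.41) and Plin2 (0.38). Those with a lower effect after LPS were Slc7a5 (-1.71), Col4a1 (-1.59), Col4a2 (-1.58), Mthfd2 (-1.57), Nuf2 (-1.54), Asns (-1.44), Pbk (-1.42), Ctps (-1.39), Sgol1 (-1.35), Cass4 (-1.35), Birc5 (-1.07), Aurka (-1.02), Cdk1 (-0.96), Bub1b (-0.63) and Tnf (-0.41).

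Without M0_siEHD1 replicate 1 the 379 higher and 356 lower effects were 243 and 210, and the lower count was 209 without M0_siCON replicate 1, 221 without M0_siEHD1 replicate 2, 235 without M1_siEHD1 replicate 1 and 236 without M1_siEHD1 replicate 3. Among the named genes, several calls rested on single libraries. Flt1 was lost without M1_siCON replicate 1 or M1_siEHD1 replicate 1 or 3 (adjusted p up to 0.079), and Iigp1 without M0_siEHD1 replicate 1 or 2 (up to 0.072). Olfr56 was lost without M0_siCON replicates 1, 2 or 3, M0_siEHD1 replicates 1 or 2 or M1_siEHD1 replicates 1 or 3 (up to 0.12). Sort1 was lost without any of M0_siCON replicates 1, 2 and 3, M0_siEHD1 replicate 1, M1_siCON replicates 1 and 3 and M1_siEHD1 replicates 2 and 3 (up to 0.12). Tnf kept its call only without M0_siCON replicate 2, M0_siEHD1 replicate 3 or M1_siCON replicate 2, and reached 0.16 otherwise. Col4a1 kept its call only without M0_siCON replicate 2 or M1_siCON replicate 3, and reached 0.11 otherwise.

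Counts over other splits bear on chance. For the difference between states, 8 of 100 splits gave as many calls as the real 735, so chance is not excluded by this count. The highest other split gave 3403 calls and exchanged the LPS-treated siRNA labels whole, which turns the difference into a sum of both effects and points to the structure of the samples. All 8, the real one included, were among the 12 splits that kept the resting libraries under their own siRNA, and the 88 that mixed them reached at most 9. Those 12 keep the resting siEhd1 effect within the difference, so the count of 8 cannot decide on chance either way. For the resting effect (3432 calls, highest other split 0), the LPS-treated effect (1039, highest other 1) and LPS with siControl (8369, highest other 0) the 10 possible splits are too few for a share under 0.05, 1 of 10 being the real one. For the averaged LPS effect, 1 of 100 splits, the real one, reached 9315 calls against 3631 for the next, a share under 0.05. Most other splits mixed resting and LPS-treated libraries within a group. That widens the spread, so their low counts came partly by construction.

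The first pattern weighed was the fall of interferon-stimulated genes in resting siEhd1 cells, where 44 of 48 genes had every siEhd1 library below every siControl library (chance gives 5% in 1 direction) and leave-one-out medians lay between -0.723 and -0.596. Direct repression through the shared 7-base sequence is not enough, since the 43 members without it in their longest annotated 3 prime UTR had a median of -0.61. Effects that reach these genes, or the cell cycle genes below, by way of other repressed genes were not tested. LPS-like stimulation of the resting siControl cultures stays open: the cytokine list, which it would lower with siEhd1, had a median of 0.36 (SE 0.22 over its members) with 10 of 27 higher and 0 lower but was not called (camera adjusted p = 0.069). Against that, the 1006 LPS-induced genes outside the interferon list included 222 lower and 120 higher (camera adjusted p = 0.036, and 0.0066 with an estimated correlation, or 0.19 without M1_siCON replicate 3), a call lost without M0_siCON replicate 2 (adjusted p = 0.12) or M0_siEHD1 replicate 3 (0.054), and with genes of like names also set aside (967 left, adjusted p = 0.04, and 0.021 with an estimated correlation, or 0.19 without M1_siCON replicate 3) it was lost without those or M0_siCON replicate 3 (0.05), while other interferon targets may remain in both sets. An interferon response to the control siRNA, which would make siControl high rather than siEhd1 low, stays open too, because 0 untransfected libraries were among the samples, and an effect of lower EHD1 on resting interferon signalling may be offered only as a hypothesis beside these.

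The next pattern was the rise of cell cycle genes. A single library standing apart does not account for it: all 34 genes were separated between the groups in resting cells and 31 after LPS, and leave-one-out medians stayed at or above 1.18 and 0.568. A lower share of macrophages stays open: of 35 markers of other cell types 6 were lower and 4 higher in resting siEhd1 cells, but 9 of the 35 lay at 5 CPM or more in resting siControl cells and 3 are held by another list, while 14 of 27 macrophage identity genes fell (camera adjusted p = 2.2e-05) and 6 of 9 osteoclast markers rose (0.0012), calls lost with an estimated correlation (adjusted p = 0.30 for both). Slower growth caused by the control siRNA stays open for want of untransfected cells (0 libraries). Faster cycling of siEhd1 cells may be a biological explanation, and no other siRNA against Ehd1 was analysed here to test it.

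The last pattern was the set of genes lower with siEhd1 in both states. If 1 siRNA seed repressed them, a single 7-base sequence in 3 prime UTRs was predicted, before the search, to have a scaled z under -5 in both states; GCCTTGT had -9.44 in resting and -11.83 in LPS-treated cells, and 1 other sequence passed, TGCCTTG (-5.45 and -5.94), which shares 6 bases with it. Length or base composition of the UTRs would favour other sequences of the same bases, but with sequences that share 6 bases set aside, the lowest z that the other 202 reached in both states was -1.81. Off-target repression by an siEhd1 strand is thus a candidate explanation for genes that carry the sequence. Genes with only its last 6 bases followed by A had median log2 fold changes of -0.043 in resting and -0.012 in LPS-treated cells. Genes with those 6 bases and no such A had -0.015 and 0.001, and genes with no match 0.009 and 0.008. The 144 genes lower in both states in the fit without carriers may include genes with such partial matches or without a searched UTR. Whether lower EHD1 also acts on the carriers, or acts on those 144 genes, stays open. The complement of GCCTTGT, ACAAGGC, occurs in coding exon 3 of Ehd1 (chromosome 19, 6294367 to 6294373, plus strand), as a sense strand of an siRNA against Ehd1 would need, but 16.9% of all 7-base sequences occur in that transcript. GCCTTGT itself, which a fully matched antisense strand with this seed would need there, does not occur in it.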

How the results depend on the processing

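The fit without GCCTTGT carriers was chosen after the result was seen, and all other alternatives were fixed before. No called result reversed direction in the alternatives run. Scaling, filters, DESeq2, limma-voom and the fits within a table kept every count of calls within 1.5 times its main value. Medians moved further: with no filter, that of LPS-induced genes in resting cells went from -0.081 to -0.043 and that of LPS-repressed genes after LPS from 0.128 to 0.076. With sets at a log2 fold change of 2 or more these were -0.138 and 0.198, and LPS-induced genes had -0.081 after LPS (from -0.046) and 0.11 for the difference (from 0.059). Leaving out carriers moved the lower count after LPS from 499 to 256 and the lower count in both states from 321 to 144; by construction those genes were removed. For LPS-repressed genes, the difference of effects (0.102) lost its call with an estimated correlation (adjusted p = 0.13), and the resting effect became called with fry (0.003), with sets at a log2 fold change of 2 or more (0.108) and with the stricter filter (0.000), and without M0_siCON replicate 1 (0.022, adjusted p = 0.021) or M0_siEHD1 replicate 3 (0.022, adjusted p = 0.04), with adjusted p from 0.01 to 0.2 over the alternatives; the cause was not tested.

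Leave-one-out ranges were 1201 to 1661 higher and 1148 to 1503 lower genes in resting cells, 304 to 500 and 303 to 477 after LPS, 243 to 429 and 209 to 418 for the difference, and 186 to 311 shared higher genes. Medians ranged from -0.019 to 0.022 for LPS-repressed genes in resting cells, 0.056 to 0.147 for their difference, 0.02 to 0.065 for the difference of LPS-induced genes (lowest without M0_siCON replicate 2) and -0.05 to -0.041 for LPS-induced genes after LPS. The lowest counts came without M0_siCON replicate 1 for both resting counts and the lower difference count, without M0_siEHD1 replicate 1 for the higher difference count, and without M1_siEHD1 replicate 1 for the LPS-treated and shared counts. Fewer libraries per fit lower power by construction.

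Correlations gave no consistent sign that replicate numbers pair siControl with siEhd1 libraries within a state, or siControl libraries across states. Deviations from group means of same-numbered siControl and siEhd1 libraries had correlations of -0.245, -0.201 and -0.412 in resting and -0.172, 0.211 and 0.0139 in LPS-treated cells, and siControl libraries across states -0.0215, -0.123 and -0.181. The siEhd1 libraries across states had 0.21, 0.456 and 0.247, each the best match of both libraries in that comparison. Matches as clean arose between other numbers too, so these values do not show pairing, and the labels do not state it. In resting cells each siControl library matched best an siEhd1 library of another number (1 with 3 at 0.425, 2 with 1 at 0.308 and 3 with 2 at 0.375). The replicate block gave 1595 higher and 1569 lower genes in resting cells, 459 and 425 after LPS and 342 and 295 for the difference, and 4541 and 4696 for the averaged LPS effect. Of 112 list tests, 44 were called, and 34 of these kept the call in every leave-one-out fit; 39 lost it with an estimated correlation. Over the list tests, fry lost 13 calls and gained 21, no filter lost 3 and gained 7, the stricter filter lost 1 and gained 3, limma-voom lost 2 and gained 3, leaving out carriers lost 1 and gained 7, the block lost 0 and gained 1, and RLE size factors changed 0. Over tests of named genes, calls lost were 16 with the block (18 within a table), 8 within a table without it, 7 with limma-voom, 4 each with DESeq2, no filter and carriers left out, 2 with RLE size factors and 0 with the stricter filter, and DESeq2 gained 1. Named genes kept their call in every leave-one-out fit in 115 of 120 cases in resting cells, 72 of 94 after LPS, 64 of 95 for the difference and 134 of 134 for LPS with siControl. Depth limits genes with few counts, such as Il6 with 0 counts in resting cells.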

Other observations

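The test of the iron hypothesis was chosen after the result was seen. Tfrc and Slc40a1 changed in opposite directions in both states. The transferrin receptor gene Tfrc rose from 35.6 to 50.6 CPM in resting cells (log2 fold change 0.51, SE 0.07, edgeR adjusted p = 2.2e-05) and from 48.6 to 75.0 CPM after LPS (0.62, SE 0.07, 9.4e-06). Slc40a1, which encodes the iron exporter ferroportin, fell from 77.5 to 34.2 CPM (-1.18, SE 0.15, 0.0002) and from 24.9 to 11.6 CPM (-1.10, SE 0.18, 0.0042). Neither carries GCCTTGT. The ferritin heavy chain gene Fth1, chosen after its values were seen, had a log2 fold change of -0.09 (SE 0.11) in resting and 0.04 (SE 0.11) in LPS-treated cells, not called in either.

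In resting cells 6 of 26 genes of the unfolded protein and integrated stress response list rose, Phgdh, Asns and Atf4 among them, and Mthfd2, Ctps and Slc7a5, which are outside that list, were chosen after their values were seen. The serine synthesis gene Phgdh (2.53 to 7.43 CPM, 1.55, SE 0.28), the asparagine synthetase gene Asns (7.64 to 16.2 CPM, 1.09, SE 0.17), the folate enzyme gene Mthfd2 (9.76 to 25.5 CPM, 1.39, SE 0.22), the CTP synthase gene Ctps (2.87 to 7.99 CPM, 1.48, SE 0.12) and the amino acid transporter gene Slc7a5 (2.33 to 7.34 CPM, 1.65, SE 0.16) were called. The transcription factor gene Atf4 rose by 0.35 (SE 0.06). After LPS, 0 of 26 genes of the stress response list were higher and 3 lower with siEhd1 (median 0.02, camera adjusted p = 0.74). Slc7a5 then stood at 3.67 and 3.54 CPM and Mthfd2 at 67.0 and 58.8 CPM, not called. The osteoclast fusion gene Ocstamp (2.30 to 8.58 CPM, 1.90, SE 0.19) and the acid phosphatase gene Acp5 (0.75, SE 0.11) rose in resting cells.

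A cellular iron shortage acting through iron-responsive elements may account for the rise of Tfrc RNA. Whether it bears on the fall of Slc40a1 RNA was not tested. Slc11a2, another gene with such an element in some of its transcripts, had log2 fold changes of 0.03 in resting and -0.01 in LPS-treated cells. Its gene counts pool transcripts with and without the element, so the explanation stays open.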
